A study of Homo sapiens with 8 samples.

How the data were processed

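RNA from cells labelled as SCC13 was labelled with biotin and hybridised to whole-transcript expression arrays. The labels put the 8 samples in 4 hairpin groups (shGFP, shRING1B, shEZH2 and shBMI1) of 2 arrays each, and the replicate numbers come from the sample titles, which begin with SCCL3 for shEZH2 and SCC13 for the others. The deposited values are log2 expression per probe set, made by the authors with RMA (background correction, quantile normalization and summary over probes), per the submitters' processing notes, which also name limma. Versions, the library of probe set definitions and the genome build are not given in the sources used here. RMA forces arrays to a common distribution, so a shift shared by most genes would not be seen. It also compresses differences of dim probe sets, so fold changes of dim genes are understated.

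The table held 53617 probe sets with values between 1.4 and 14.5, 0 missing values and 0 pairs of identical arrays. Probe sets were named through the annotation table of the array, with symbols updated through a RefSeq gene table. In it 16098 probe sets had 1 symbol, 0 had several and 37519 had none and were left out of the tests by gene. Where a gene had several probe sets (779 genes), the one with the highest mean over all arrays was used. This left 14884 genes, 11915 of them protein-coding. Many well-known genes, including BMI1 and RNF2, are unnamed here for this reason, and gene lists were tested on their measured members only.

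The spread was estimated with limma 3.58.1 in R 4.3.3, with a mean per group over all 8 arrays (4 residual degrees of freedom), empirical Bayes moderation without trend and no intensity filter. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided and adjusted within each comparison, were called. Each of the 3 knockdowns was compared with shGFP and with the other knockdowns. Errors given after a log2 fold change are standard errors of this fit, and errors after a group mean are SDs.

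Before the data were examined, 33 gene lists were written from general knowledge of keratinocytes, Polycomb targets, inflammation, stress and other cell types that a culture could hold, with chemokines, cytokines, NF-kB targets, interferon-response genes and antigen presentation genes as the 5 main lists. Lists with at least 4 measured members (30 lists) were tested with camera, with its preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, one way, and its mixed form whether they change in either direction. Neither compares the list with other genes.

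The genes named in the text follow a rule set before the data were examined. It takes the 3 targeted genes. Among called genes whose knockdown arrays both lie on one side of both control arrays, it takes the 10 with the largest increase and the 10 with the largest decrease (5 in each direction between knockdowns). Uncharacterised, small RNA, antisense, olfactory receptor and keratin-associated symbols are left out. With fewer than 5 called in a direction, genes with the smallest p-values fill up to 5 and are given as values. It also takes up to 4 members of each called list and the 3 members of each main list with the largest change. Any other gene is said to have been chosen after its value was seen.

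Chance agreement between comparisons that share the shGFP arrays was estimated from 100 simulated pairs of unchanged groups. The noise of each gene and array was drawn independently. The control pair was not split, since each part would hold 1 array. The fitting steps were tested on simulated data with 200 changed genes among 14884. In the simulated shRING1B, shEZH2 and shBMI1 comparisons with shGFP, 42%, 48% and 54% of genes changed by 0.5 log2 units were called, and 98%, 100% and 98% of those changed by 1. Of the calls made, 5.03%, 6.42% and 7.33% were unchanged genes. A list shifted by 0.3 was recovered by camera in each of the 3. With an estimated correlation its adjusted p was 0.138, 0.0394 and 0.0289. Of 29 unshifted lists, camera with the preset correlation called 0, 0 and 1 in the same order. Noise was drawn independently for each gene and array here too. These counts therefore do not show how often camera errs on lists whose genes vary together.

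Alternatives fixed before the data were examined were the replicate number as a block, only the arrays compared, the shEZH2 arrays left out, quantile normalization, median centring, a filter on the dimmest 30% of genes, the mean of a gene's probe sets, a trended robust variance, array weights, a minimum change of 1 log2 unit, and leaving out each array in turn. Protein-coding genes alone, all probe sets, and lists without their largest member were added after seeing the data. The closing section gives their effect. An unadjusted threshold for overlaps was also added then; its counts are not given, because the simulated lists were shorter than the observed ones. No genome was used, and no coordinates are given.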

Results

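Gene expression was measured on 8 microarrays of cells labelled as SCC13, an established line from a human cutaneous squamous cell carcinoma. The cells carried 1 of 4 short hairpin RNAs, with 2 arrays per hairpin. The shGFP hairpin, aimed at a jellyfish protein the cells do not make, was the control. The other hairpins were aimed at 3 Polycomb proteins, which keep genes silent through marks on histones. BMI1 and RING1B (gene RNF2) belong to Polycomb repressive complex 1, which ubiquitinates histone H2A. EZH2 is the histone H3 methyltransferase of Polycomb repressive complex 2. The title of the series puts the question as one about inflammatory genes, so lists of chemokines, cytokines, NF-kB targets, interferon-response genes and antigen presentation genes were set as the main lists. Of 53617 probe sets, 16098 were paired with 1 gene symbol, and 14884 genes were tested. Array medians over all probe sets lay between 5.49 and 5.52 on the log2 scale. The labels do not say whether the 2 arrays of a hairpin came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. With 2 arrays per group an exact two-sided permutation test cannot go below p = 0.333, so limma's moderated test across all genes was used, and the number of arrays limits its precision.

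EZH2 mRNA fell on the arrays of its own hairpin. Its mean was 8.99 ± 0.05 (SD, n = 2) with shEZH2 and 9.90 ± 0.10 (SD, n = 2) with shGFP. The log2 fold change was -0.91 ± 0.12 (SE; adjusted p = 0.0183), a 1.88-fold lower level. With shRING1B and shBMI1 the log2 fold change of EZH2 was -0.16 ± 0.12 (adjusted p = 0.789) and -0.06 ± 0.12 (adjusted p = 0.999), and neither passed the test. BMI1 and RNF2 were not analysed here, because no probe set is paired with either symbol in the annotation used. The knockdowns by shBMI1 and shRING1B were therefore not checked. The titles of the shEZH2 arrays begin with SCCL3, where those of the other 6 arrays begin with the line name SCC13, although the cell line field reads SCC13 for all 8. Gene values of the shEZH2 arrays correlated with those of the other arrays at 0.992 to 0.993, and the 2 arrays of a hairpin at 0.995 to 0.996. Among the other 6 arrays, those of different hairpins correlated at 0.993 to 0.996, so the lowest of these lay close to the shEZH2 values. No array of another line was analysed here, so the identity of the cells was not checked. Another cell line or a batch that goes with this prefix cannot be told apart from the shEZH2 hairpin, and this applies to every shEZH2 value.

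With shEZH2, single genes of inflammation (CCL20, C3), antimicrobial defence (S100A8, SLPI) and amino acid synthesis (ASNS, PSAT1) rose, and the replication genes MCM5 and MCM10 fell. The largest increase was in AMTN, a tooth enamel matrix protein, which rose 5.48-fold (log2 2.45 ± 0.22 SE, n = 2 per group, adjusted p = 0.00608). CCL20, a chemokine that draws dendritic cells and lymphocytes, rose 3.25-fold (log2 1.70 ± 0.24, adjusted p = 0.026). The tight junction protein CLDN1 rose 2.66-fold and the growth factor FGF2 rose 2.67-fold, with adjusted p = 0.0159 and 0.0345. The complement protein C3 rose 2.34-fold (adjusted p = 0.0329) and the alarmin S100A8 rose 2.30-fold (adjusted p = 0.00868).

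**Figure D1:**
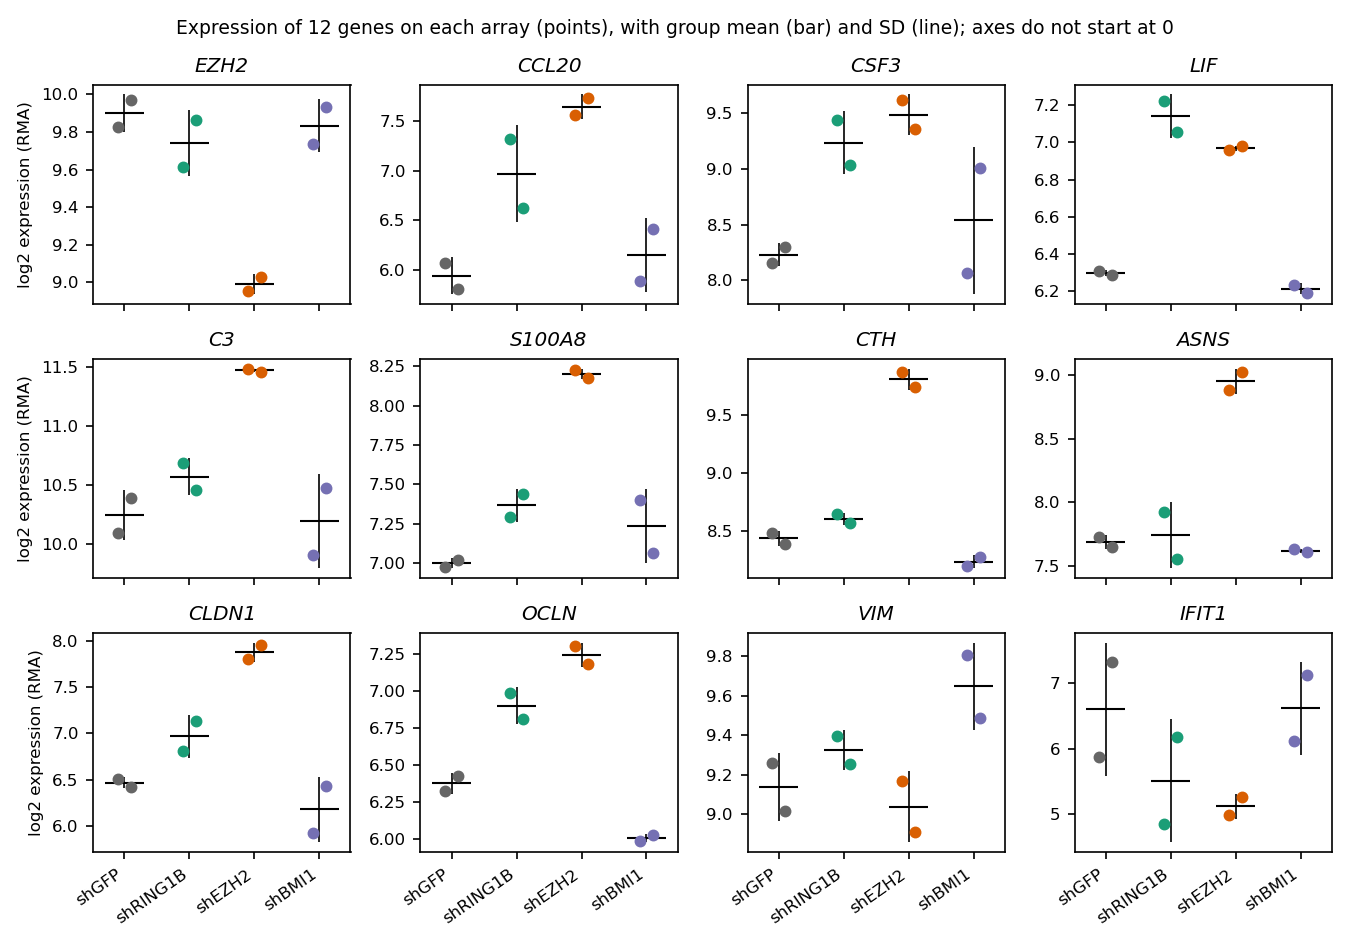
Log2 expression (RMA) of 12 genes on each of the 8 arrays. Points are arrays, the horizontal bar is the mean of a hairpin's 2 arrays and the vertical line its SD; axes do not start at 0. EZH2 was lowest on the shEZH2 arrays (mean 8.99), and IFIT1 spread over a wide range within shGFP (5.87 and 7.31).

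In all, 109 genes passed the adjusted threshold with shEZH2, 83 higher and 26 lower. Of these, 30 rose and 2 fell by a log2 change of at least 1. Other large increases were in STC2 (log2 1.48 ± 0.17), PSAT1 (1.38 ± 0.16), LURAP1L (1.37 ± 0.09), EBI3 (1.35 ± 0.17) and ASNS (1.27 ± 0.13), and CTH, which makes cysteine from cystathionine, rose 2.57-fold. Among the decreases, CD274, which encodes the immune checkpoint ligand PD-L1, fell by 0.68 ± 0.10 (SE; adjusted p = 0.0243) on the log2 scale. ANO4 fell by 0.93 ± 0.08, GAS6 by 0.85 ± 0.09, the protocadherin PCDH7 by 0.74 ± 0.09 and the microfibril protein FBN2 by 0.69 ± 0.09. MT1L gave the largest decrease, -1.72 ± 0.16, and is uncertain because metallothionein genes have near-identical copies. The count rested on every array. It was 19 without shGFP replicate 1, 6 without shGFP replicate 2 and 0 without either shEZH2 array. It was 39 with only the 4 arrays compared, 4 over all probe sets, 409 without the dimmest 30% of genes, 648 with a trended robust variance, 174 with array weights and 169 over protein-coding genes alone. The split into higher and lower genes moved too. It was 222 higher and 187 lower without the dimmest genes, 281 higher and 367 lower with the trended robust variance, and 1121 higher and 1287 lower at an unadjusted p under 0.05.

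**Figure D2:**
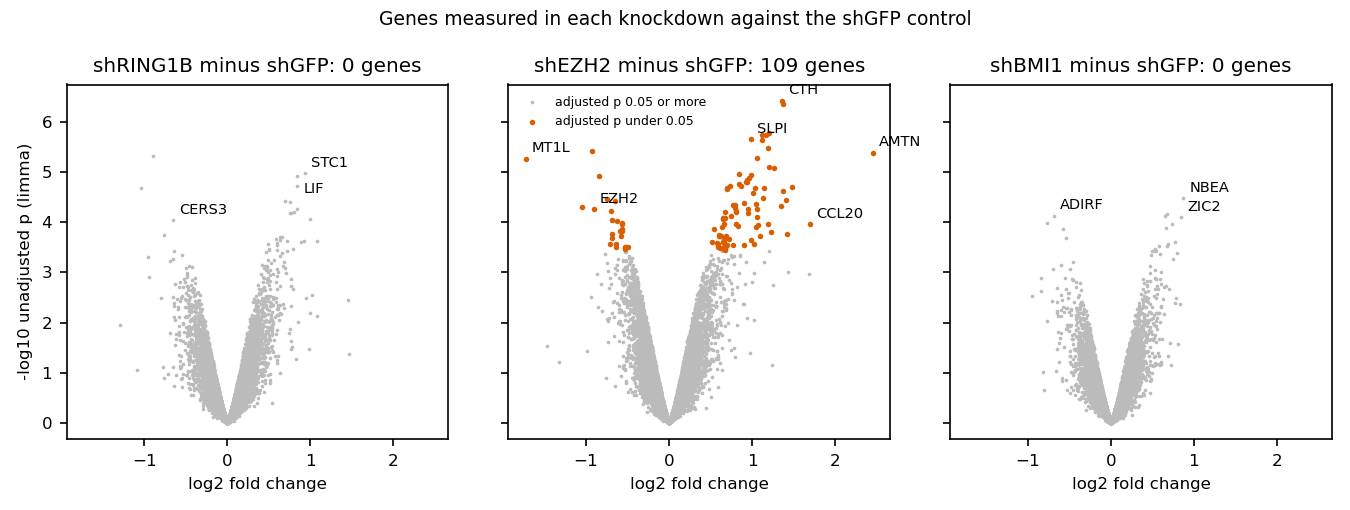
Log2 fold change (x axis) against -log10 of the unadjusted limma p (y axis) for 14884 genes in each knockdown against shGFP. Coloured points have an adjusted p under 0.05; they number 109 with shEZH2 and 0 with shRING1B and with shBMI1.

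Among the main lists with shEZH2, chemokines, cytokines and NF-kB targets were higher by camera, a test of a list against all other genes, with its preset correlation but not with an estimated one. Of 22 measured cytokine genes, 3 rose over all genes and 9 rose adjusted over the list alone (list adjusted p = 1.1e-05; adjusted p = 0.164 with an estimated correlation). They included IL32 (log2 0.97 ± 0.10, adjusted p = 0.0109), EBI3 and the interleukin 6 family member LIF (0.67 ± 0.09, adjusted p = 0.0191). The granulocyte growth factor CSF3 was at 1.25 ± 0.27 and IL24 at 1.03 ± 0.30, and neither passed over all genes (adjusted p = 0.09 and 0.162). Of 25 NF-kB targets, C3 and the complement factor CFB (0.74 ± 0.08, adjusted p = 0.0109) rose over all genes, 10 rose adjusted over the list alone and 22 had positive values (list adjusted p = 1.36e-08; adjusted p = 0.226 with an estimated correlation). SAA1 (1.02 ± 0.20) and IRAK2 (0.64 ± 0.14) did not pass over all genes. Of 28 chemokines, CCL20 rose over all genes and 4 rose adjusted over the list alone (list adjusted p = 0.0237; adjusted p = 0.194 with an estimated correlation). CXCL8 was at 0.90 ± 0.23, CCL3 at 0.66 ± 0.17 and CXCL3 at 0.64 ± 0.17, without passing over all genes. The chemokine call with the preset correlation was also lost without shGFP replicate 1 (adjusted p = 0.231), without shEZH2 replicate 1 (0.0954), without its largest member (0.0758), after quantile normalization (0.0874) and without the dimmest genes (0.0563). Leukocyte markers were higher on the same arrays, with a median of 0.25 over 9 measured genes, 0 of them past the threshold (list adjusted p = 0.00464; adjusted p = 0.179 with an estimated correlation).

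The interferon-response and antigen presentation lists did not pass with shEZH2. The interferon list had a median of -0.06 over 35 genes (adjusted p = 0.5), and 0 genes passed over all genes or adjusted over the list alone. IFIT1, IFIT2 and IFIT3 were at -1.47 ± 0.56, -0.99 ± 0.40 and -0.76 ± 0.45. This list depended on which control array was used. Without shGFP replicate 1 the list was lower with shEZH2 (adjusted p = 0.00193), and without shGFP replicate 2 its direction turned upward without passing (adjusted p = 0.13). The antigen presentation list had a median of -0.02 over 6 measured genes (adjusted p = 0.804), with ERAP2 at -0.30 ± 0.13, B2M at -0.19 ± 0.11 and TAPBP at 0.16 ± 0.09.

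Outside the main lists, the lowest list p-value with shEZH2 was that of stress genes under the transcription factor ATF4 and the unfolded protein response. Of 12 measured members, 7 rose over all genes, 10 rose adjusted over the list alone and all 12 had positive values (list adjusted p = 5.23e-14; adjusted p = 0.164 with an estimated correlation). ASNS and PSAT1, enzymes of asparagine and serine synthesis, STC2 and the pseudokinase TRIB3 (log2 1.05 ± 0.13) led the list. Of 8 antimicrobial and S100 genes, 4 rose over all genes and 6 adjusted over the list alone (list adjusted p = 8.92e-09; adjusted p = 0.159 with an estimated correlation). They were S100A8 (1.20 ± 0.12), the protease inhibitor SLPI (0.98 ± 0.08), S100A9 (0.96 ± 0.13) and S100A7 (0.90 ± 0.11). Of 24 epithelial junction genes, CLDN1, CLDN7 (1.06 ± 0.14) and OCLN (0.87 ± 0.10) rose, and 3 rose adjusted over the list alone (list adjusted p = 0.00193; adjusted p = 0.179 with an estimated correlation). Of 15 cholesterol synthesis genes, the sterol carrier STARD4 rose (0.65 ± 0.10, adjusted p = 0.0423), with 1 gene past the threshold adjusted over the list alone (list adjusted p = 0.0103). That list's adjusted p was 0.411 with an estimated correlation and 0.0539 without its largest member.

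The 2 cell cycle lists were lower with shEZH2 by camera with the preset correlation, though not with an estimated one, and 2 of their genes passed over all genes. All 24 measured G1/S genes had negative values, with a median of -0.30. MCM5 and MCM10, parts of the replication machinery, fell by 0.57 ± 0.08 and 0.53 ± 0.09 (adjusted p = 0.0312 and 0.0457), and 16 genes fell adjusted over the list alone (list adjusted p = 8.42e-12; adjusted p = 0.194 with an estimated correlation). Of 24 G2/M genes, 23 had negative values, 0 passed over all genes and 9 fell adjusted over the list alone (list adjusted p = 5.32e-10; adjusted p = 0.284 with an estimated correlation). MKI67 was at -0.47 ± 0.10 and AURKB at -0.45 ± 0.09. Ribosomal protein genes, kept as a quality list, were lower with a median of -0.13 over 14 genes, 0 of them past either threshold (list adjusted p = 0.0179). For this list the adjusted p was 0.411 with an estimated correlation, 0.339 without shEZH2 replicate 2 and 0.0621 without shGFP replicate 1.

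**Figure D3:**
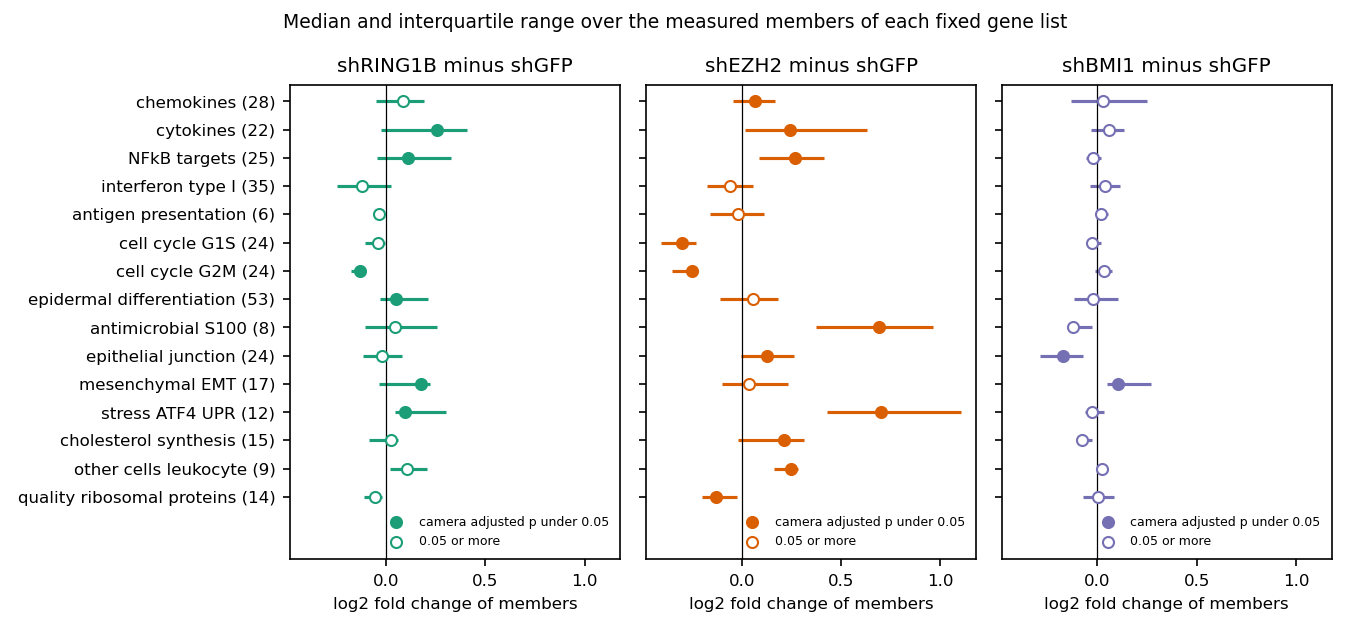
Median (point) and interquartile range (line) of the log2 fold change over the measured members of each fixed gene list, for each knockdown against shGFP; the number of members is in parentheses. Filled points have a camera adjusted p under 0.05 with the preset correlation. The ATF4 stress list had a median of 0.70 with shEZH2 and 0.10 with shRING1B.

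With shRING1B, no single gene passed. Among the smallest p-values outside small RNA genes, STC1, which encodes the secreted glycoprotein stanniocalcin, was 1.91-fold higher (log2 0.94 ± 0.10 SE, n = 2 per group) and LIF 1.79-fold higher (0.84 ± 0.09), each with adjusted p = 0.0598 by limma. HEPHL1 was at 0.84 ± 0.09 (adjusted p = 0.0628), and CACHD1 and LURAP1L were at 0.70 ± 0.09 and 0.76 ± 0.09 (both adjusted p = 0.0844). The chemokines CCL20 and CXCL8 were at 1.03 ± 0.24 and 0.95 ± 0.23, and CSF3 was at 1.00 ± 0.27. Among lower values were CERS3, a ceramide synthase of the skin barrier, at -0.65 ± 0.09, CCN6 at -0.76 ± 0.12 and CLCA2 at -0.95 ± 0.17. At an unadjusted p under 0.05 there were 1280 genes, where chance gives 744.2. The count of 0 became 11 without the dimmest 30% of genes, 36 with a trended robust variance and 9 over protein-coding genes alone, and STC1, LIF, HEPHL1, CACHD1 and LURAP1L passed in each of these.

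As lists, cytokines and NF-kB targets were higher with shRING1B by camera with the preset correlation but not with an estimated one. Of 22 cytokine genes, 0 passed over all genes and 4 rose adjusted over the list alone (list adjusted p = 0.000277; adjusted p = 0.403 with an estimated correlation). Besides LIF and CSF3, IL32 was at 0.45 ± 0.10, IL24 at 0.78 ± 0.30 and IL37 at 0.46 ± 0.13. Of 25 NF-kB targets, 18 had positive values and 2 rose adjusted over the list alone (list adjusted p = 0.00455; adjusted p = 0.552 with an estimated correlation). PTGS2, the inducible cyclooxygenase, was at 0.55 ± 0.14, IRAK2 at 0.47 ± 0.14, SAA1 at 0.45 ± 0.20 and the deubiquitinase CYLD, which restrains NF-kB signalling, at 0.37 ± 0.08. The NF-kB call was lost without shGFP replicate 1 (adjusted p = 0.177) and without shRING1B replicate 1 (0.195). The chemokine list did not pass (median 0.08 over 28 genes, adjusted p = 0.055; 2 genes passed adjusted over the list alone), but did without shGFP replicate 2 (0.0176) and with only the 4 arrays compared (0.0309).

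Without a replicate block, the interferon-response list did not pass with shRING1B either (median -0.12 over 35 genes, adjusted p = 0.055). IFIT2, IFIT1 and IFIT3 were at -1.29 ± 0.40, -1.08 ± 0.56 and -0.76 ± 0.45, and 0 genes passed adjusted over the list alone. The list was lower, past the threshold, without shGFP replicate 1 (adjusted p = 5.35e-06) and without shRING1B replicate 2 (0.000445). Without shGFP replicate 2 its direction turned upward. On this list replicate 2 lay above replicate 1 by 0.40 with shGFP and 0.31 with shRING1B, so leaving out 1 array unbalances the replicates. Relative to all arrays, the list mean was -0.27 with shRING1B and -0.14 with shGFP in replicate 1, and 0.04 and 0.27 in replicate 2. With the replicate number as a block the list was lower by camera with the preset correlation (adjusted p = 0.00868). The labels do not say that equal numbers mark a shared batch. The antigen presentation list had a median of -0.04 over 6 genes (adjusted p = 0.554), with ERAP2 at -0.19 ± 0.13, TAPBP at -0.05 ± 0.09 and CANX at -0.04 ± 0.10.

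Other lists past the threshold with shRING1B moved by small amounts. All 24 G2/M genes had negative values with a median of -0.13, and 0 passed over all genes or adjusted over the list alone (list adjusted p = 1.99e-05; adjusted p = 0.55 with an estimated correlation). CDK1 was at -0.32 ± 0.11 and MKI67 at -0.22 ± 0.10. Of 12 ATF4 stress genes, 4 rose adjusted over the list alone, with TRIB3 and STC2 both at 0.55 (list adjusted p = 0.0122; adjusted p = 0.55 with an estimated correlation). Mesenchymal genes (TNC at 0.46 ± 0.08, AXL at 0.44 ± 0.09) had 3 genes higher and 1 lower adjusted over the list alone. Epidermal differentiation genes (KLK7 at 1.46 ± 0.36, CNFN at 0.74 ± 0.24) had 0. Both lists had an adjusted p of 0.0351, and of 0.403 with an estimated correlation. Without shRING1B replicate 1 the adjusted p was 0.183 for G2/M genes, 0.663 for ATF4 stress genes, 0.183 for mesenchymal genes and 0.068 for epidermal differentiation genes. Without shGFP replicate 2 it was 0.187 for ATF4 stress genes and 0.0956 for mesenchymal genes. Without shGFP replicate 1 it was 0.108 for mesenchymal and 0.181 for epidermal differentiation genes, and without shRING1B replicate 2 it was 0.0709 and 0.108.

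With shBMI1, epithelial junction genes were lower and mesenchymal genes higher as lists with the preset correlation but not with an estimated one, while 0 single genes passed. Of 24 epithelial junction genes, 21 had negative values with a median of -0.18, and 4 fell adjusted over the list alone (list adjusted p = 4.76e-06; adjusted p = 0.118 with an estimated correlation). The desmosomal cadherin DSG3 was at -0.48 ± 0.13, the membrane protease ST14 at -0.46 ± 0.08, MARVELD3 at -0.40 ± 0.11 and OCLN at -0.37 ± 0.10 (n = 2 per group). Of 17 mesenchymal genes, 14 had positive values with a median of 0.11, and 3 rose adjusted over the list alone (list adjusted p = 3.35e-05; adjusted p = 0.118 with an estimated correlation). The transcription factor ZEB2 was at 0.53 ± 0.09, CCN2 at 0.53 ± 0.12 and the intermediate filament protein VIM at 0.51 ± 0.15.

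No gene passed with shBMI1 by limma (smallest adjusted p = 0.223), and 830 genes had an unadjusted p under 0.05, where chance gives 744.2. The smallest p-values belonged to NBEA (0.87 ± 0.11), ZFHX4 (0.68 ± 0.09), JAM3 (0.66 ± 0.09) and ZIC2 (0.85 ± 0.12) among positive values, and to ADIRF (-0.69 ± 0.09), RSPH10B2 (-0.77 ± 0.11) and RASEF (-0.58 ± 0.09) among negative ones. None of the 5 main lists passed. Their adjusted p was 0.604 for chemokines, 0.393 for cytokines, 0.759 for NF-kB targets, 0.302 for interferon-response genes and 0.759 for antigen presentation. CSF3 was at 0.31 ± 0.27, IL15 at 0.60 ± 0.12, CXCL10 at 0.72 ± 0.34 and CCL7 at 0.83 ± 0.21. The interferon list was higher, past the threshold, without shBMI1 replicate 1 (adjusted p = 0.00425) and without shGFP replicate 2 (2.91e-06). Its direction turned downward when shGFP replicate 1 or shBMI1 replicate 2 was left out. On this list replicate 2 lay above replicate 1 by 0.40 with shGFP and 0.30 with shBMI1. With the replicate number as a block the list did not pass by camera (adjusted p = 0.136). In simulated data of this design with 200 changed genes, 98% of genes changed by 1 log2 unit were called in this comparison. Of those changed by 0.5, 54% were called. With that many changed genes the adjustment is easier to pass, so these rates do not carry over to the measured comparison. There NBEA and ZIC2, at 0.87 and 0.85, did not pass, so the lack of calls does not exclude changes of this size.

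The knockdowns were also set against each other, which tests whether they differ. Between shEZH2 and shBMI1, 145 genes differed, 103 higher and 42 lower with shEZH2. AMTN (2.03 ± 0.22), CLDN1 (1.70 ± 0.17), CTH (1.56 ± 0.09), and STC2 (1.51 ± 0.17) were higher with shEZH2, S100A7 was 2.82-fold higher, and ANO4 (-1.43 ± 0.08), the proteoglycan SRGN (-1.27 ± 0.18) and IGF2BP1 (-0.86 ± 0.09) were lower. Between shRING1B and shEZH2, 86 genes differed, 33 higher and 53 lower with shRING1B. SRGN (1.62 ± 0.18), TMEM200A (1.27 ± 0.18) and the actin-bundling protein LCP1 (1.23 ± 0.12) were higher with shRING1B, and AMTN (-1.90 ± 0.22), PSAT1 (-1.36 ± 0.16), ASS1 (-1.29 ± 0.15) and ASNS (-1.21 ± 0.13) were lower. Between shRING1B and shBMI1, 2 genes passed by limma, both higher with shRING1B: LIF (0.93 ± 0.09) and the hair keratin-associated KRTAP2-3 (1.13 ± 0.11), the latter named after its value was seen; both had an adjusted p of 0.0439. There, 1367 genes had an unadjusted p under 0.05. By camera with the preset correlation, cytokines (adjusted p = 0.0312) and NF-kB targets (0.0026) were higher with shRING1B than with shBMI1, and interferon-response genes lower (0.00113). Chemokines (0.335) and antigen presentation genes (0.304) did not pass. With an estimated correlation cytokines and NF-kB targets were at 0.522, and the value for interferon-response genes is not given here. Leaving out arrays moved the gene counts. The 145 genes became 18 and 35 without shBMI1 replicates 1 and 2, and 2 and 11 without shEZH2 replicates 1 and 2. The 86 genes became 14 and 2 without shRING1B replicates 1 and 2, and 0 and 1 without shEZH2 replicates 1 and 2. The 2 genes became 0 without any 1 of the 4 arrays and with the shEZH2 arrays left out of the fit.

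The fold changes of the knockdowns were compared over all 14884 genes. Across genes, which are not independent replicates, those of shRING1B and shEZH2 had a Pearson r of 0.421. Comparisons that share control arrays correlate without any effect, and 100 simulated pairs of unchanged groups gave a mean r of 0.499 (range 0.481 to 0.518), above the observed value. The covariance was 0.0153 against a mean of 0.00833 in the simulation, a difference of 0.00697. It lay above the simulated range for the other pairs too, by 0.00221 over the mean for shRING1B with shBMI1 (r = 0.418) and 0.00298 for shEZH2 with shBMI1 (r = 0.357). Between shRING1B minus shGFP and shEZH2 minus shBMI1, which share no array, r was 0.131, and the simulated range was -0.0357 to 0.0284. For the other such pairs r was 0.108 (shEZH2 minus shGFP with shRING1B minus shBMI1; simulated -0.0231 to 0.0344) and -0.024 (shBMI1 minus shGFP with shRING1B minus shEZH2; simulated -0.0263 to 0.0296). The r of 0.108 again sets shRING1B beside shEZH2. In the last pair shEZH2 is subtracted, so an effect shared by shEZH2 and shBMI1 would make r negative.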

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

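Of the tests in this part, those on a separate culture or RNA batch, on the strength of the BMI1 and RING1B knockdowns, and on the ATF4 stress list with shEZH2 and the cytokine list with shRING1B against shBMI1 were chosen only after the result was seen. The search of probe sets without a gene symbol, which the comparisons by gene do not use, found 1 past the threshold in shEZH2 minus shGFP. This probe set, 16976615, had a log2 fold change of 1.86 ± 0.13 (SE, adjusted p = 0.0325 over 37519 probe sets); no biological explanation was tested.

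More genes passed with shEZH2 (109) than with shRING1B or shBMI1 (0 each). On the dimmest 30% of all probe sets, the ratio of between-group to within-group mean square was 1.05 for shEZH2 and at most 1.06 for the other hairpins. These probe sets lie near the floor and no hairpin moved them, so the test cannot tell whether a hybridisation or scan batch is present, and this stays open. A separate culture or RNA batch, or another cell line, cannot be told apart from the hairpin, because 0 arrays of another hairpin share the title prefix of the shEZH2 arrays (SCCL3, against SCC13). Weaker knockdown of BMI1 or RING1B than of EZH2 also stays open, since 0 named probe sets of BMI1 and RNF2 were analysed, and so does a larger role of EZH2 in these cells.

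The ATF4 stress, cytokine and NF-kB lists were higher with both shRING1B and shEZH2 by camera with the preset correlation, but with an estimated one the adjusted p was 0.55, 0.403 and 0.552 with shRING1B and 0.164, 0.164 and 0.226 with shEZH2. Low values on the shGFP arrays would not raise them against shBMI1, yet there camera in limma gave, in that order, adjusted p = 0.027, 0.0312 and 0.0026 with shRING1B (0.0054, 0.00727 and 0.00026 before adjustment) and adjusted p = 2.21e-13, 0.000864 and 2.34e-09 with shEZH2 (7.38e-15, 0.000231 and 4.69e-10 before adjustment). This argument too rests on the preset correlation: against shBMI1, with an estimated one, the adjusted p was 0.522 for each list with shRING1B, and 0.165, 0.201 and 0.201 with shEZH2. Leukocytes in the shEZH2 cultures are a candidate source that stays open. The median of the 9 measured leukocyte markers was 0.25, though none passed over all genes and 4 were among the dimmest genes. LAPTM5 (0.31 ± 0.15) and TYROBP (0.28 ± 0.12) were raised by over 2 SE, and CD14 (0.27 ± 0.23) was not. These are the 3 taken as abundant, but their mean levels lay at the 38.4, 51.4 and 42.5 percentile of genes. SRGN, abundant in blood cells but outside this list, went the other way, at -1.27 ± 0.18 with shEZH2 against shBMI1. SRGN was bright with both hairpins (8.99 and 10.26), so its fall cannot tell whether leukocytes were present. A response of the carcinoma cells to both knockdowns remains a hypothesis.

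The fold changes of shRING1B and shEZH2 were correlated across genes, though r (0.421) lay below the 0.481 to 0.518 of simulated unchanged groups that share controls. Between shRING1B minus shGFP and shEZH2 minus shBMI1, which share no array, r was 0.131, above the simulated -0.0357 to 0.0284. The simulation drew the noise of each gene and array independently, however. Differences of replicate 2 from replicate 1, which hold no hairpin effect, correlated at 0.000656 (shRING1B with shEZH2) to 0.248 (shBMI1 with shGFP) between hairpins. What goes with the replicate number cancels between group means, so this is no reference range for the r of 0.131. At 0.248 the noise was not independent between arrays, so the simulated range may be too narrow. The r of 0.131 is therefore not read as an effect of the knockdowns. The covariance (0.0153) lay above the simulated 0.00785 to 0.00896, but so did that of shEZH2 with shBMI1 (0.0113 against 0.00786 to 0.00904). Without shared arrays, shBMI1 minus shGFP with shRING1B minus shEZH2 had an r of -0.024 (simulated -0.0263 to 0.0296). As shEZH2 is subtracted there, an effect shared by shEZH2 and shBMI1 would make r negative, and the value lay within the simulated range. The covariance is therefore not used as an argument. A culture condition common to the shRING1B and shEZH2 arrays, or to the shGFP and shBMI1 arrays, was not tested. Whether both knockdowns share effects stays open, and so does the part of the shared shGFP arrays.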

How the results depend on the processing

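Protein-coding genes alone, all probe sets and lists without their largest member were chosen after seeing the data. The cause of each change below was not tested, except that leaving out arrays or pooling fewer of them leaves fewer degrees of freedom and that testing fewer or more probe sets changes the adjustment. Dim probe sets limit what can be seen. Most counts were higher without the dimmest genes, but testing fewer genes also eases the adjustment, so this does not show an effect of dimness.

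The count of genes with shEZH2 against shGFP (109) was 32 with a log2 change of at least 1 as well, 39 with only the arrays compared, 409 without the dimmest genes, 648 with a trended robust variance, 174 with array weights, 169 over protein-coding genes and 4 over all probe sets. Of the 109, 83 were higher and 26 lower, against 222 and 187 of the 409 and 281 and 367 of the 648. Of the 109, 99 remained among the 409 and 108 among the 648. Array weights came out equal for both arrays of a hairpin, so they weight hairpins. For shRING1B against shGFP (0) the counts were 11 without the dimmest genes, 36 with a trended robust variance and 9 over protein-coding genes. For shBMI1 against shGFP every alternative gave 0. For shRING1B against shBMI1 (2) they were 18 without the dimmest genes, 38 with a trended robust variance, 1 with a log2 change of at least 1, and 0 with only the arrays compared, median centring, array weights, all probe sets or the shEZH2 arrays out of the fit. For shRING1B against shEZH2 (86) they were 21 with a log2 change of at least 1, 21 with only the arrays compared, 361 without the dimmest genes, 555 with a trended robust variance, 183 over protein-coding genes and 4 over all probe sets. For shEZH2 against shBMI1 (145) they were 36, 57, 445, 640, 320 and 9 in the same order. Leaving out 1 array gave 0 to 19 for shEZH2 against shGFP, 0 to 0 for shRING1B and shBMI1 against shGFP and for shRING1B against shBMI1, 0 to 14 for shRING1B against shEZH2 and 2 to 35 for shEZH2 against shBMI1. The lone array of a group was then assumed to vary like the other groups.

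The samples share only a replicate number: deviations of same-numbered arrays correlated at 0.000656 to 0.248 between groups. With the replicate number as a block, 108 genes passed with shEZH2 against shGFP (88 of the 109 remained), 0 with shRING1B against shBMI1, and the interferon list with shRING1B had an adjusted p of 0.00868. Among the main and the called lists, the block changed no other call, and it moved no other count by over 1.5 times. The remaining lists were not tested with the block.

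Every list called with the preset correlation was lost with an estimated one. With shRING1B the adjusted p was then 0.403 for cytokines, epidermal differentiation and mesenchymal genes, 0.552 for NF-kB targets and 0.55 for G2/M and ATF4 stress genes. With shEZH2 it was 0.194 for chemokines and G1/S genes, 0.164 for cytokines and ATF4 stress genes, 0.226 for NF-kB targets, 0.284 for G2/M genes, 0.159 for antimicrobial genes, 0.179 for epithelial junction genes and leukocyte markers, and 0.411 for cholesterol synthesis and ribosomal protein genes. With shBMI1 it was 0.118 for both lists. A lost call does not by itself show that the genes of a list vary together. The estimated correlation was below the preset 0.01 for mesenchymal genes (-0.0266), leukocyte markers (-0.0732), epidermal differentiation (0.000165) and chemokines (0.000806). For the other called lists it was above 0.01. It was 0.402 for G2/M, 0.297 for ATF4 stress, 0.294 for G1/S genes and 0.232 for NF-kB targets. It was 0.218 for cholesterol synthesis, 0.18 for ribosomal protein, 0.044 for antimicrobial, 0.0341 for cytokine and 0.0169 for epithelial junction genes. In the simulated shRING1B comparison, a list shifted by 0.3 was also missed with an estimated correlation (adjusted p = 0.138). Fry did not call, with shRING1B, cytokines (0.121), NF-kB targets (0.351), G2/M (0.245), epidermal differentiation (0.245), mesenchymal (0.117) and ATF4 stress genes (0.343). With shEZH2 it did not call chemokines (0.0606), cholesterol synthesis (0.138) and ribosomal protein genes (0.12), and with shBMI1 epithelial junction genes (0.0674). Its mixed form called 12, 25 and 5 of 30 lists with shRING1B, shEZH2 and shBMI1.

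Quantile normalization ended the calls of epidermal differentiation with shRING1B (0.101) and of chemokines (0.0874) and ribosomal protein genes (0.098) with shEZH2. Without the largest member, the adjusted p was 0.0826 for epidermal differentiation, 0.0931 for mesenchymal and 0.0581 for ATF4 stress genes with shRING1B, and 0.0758 for chemokines, 0.0539 for cholesterol synthesis and 0.0546 for ribosomal protein genes with shEZH2. Without the dimmest genes, chemokines with shEZH2 were at 0.0563. With only the arrays compared, chemokines with shRING1B passed (0.0309). Directions of uncalled lists turned for antigen presentation with shEZH2 under quantile normalization (0.984) and without its largest member (0.772), and for chemokines with shBMI1 without the dimmest genes (0.728).

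Leaving out 1 array gave these ranges of adjusted p with shRING1B: NF-kB targets 0.000694 to 0.195, G2/M 7.54e-08 to 0.183, epidermal differentiation 0.0202 to 0.181, mesenchymal 0.0709 to 0.183, ATF4 stress 0.000271 to 0.663, interferon 5.35e-06 to 0.986, chemokines 0.0176 to 0.381 and antigen presentation 0.244 to 0.927. With shEZH2 they were 0.00268 to 0.231 for chemokines, 0.000593 to 0.339 for ribosomal proteins, 0.481 to 0.908 for antigen presentation and 0.00193 to 0.601 for interferon genes. With shBMI1 they were 0.0594 to 0.53 for NF-kB targets, 2.91e-06 to 0.719 for interferon genes and 0.38 to 0.906 for antigen presentation. The other called lists kept their call without any 1 array.

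Without the dimmest genes the correlation of fold changes was 0.402 for shRING1B with shEZH2, 0.367 for shRING1B with shBMI1 and 0.272 for shEZH2 with shBMI1.

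Of 2342 recomputed values of named genes, 2044 kept their direction and side of the threshold, 215 lost a call, 70 gained one and 13 turned sign. All 13 were uncalled genes and came from leaving out 1 array. The log2 ranges were -0.11 to 0.0158 for TAPBP and -0.10 to 0.0138 for CANX with shRING1B. With shBMI1 they were -0.16 to 0.0343 for EZH2, -0.47 to 0.17 for SAA1, -0.31 to 0.0211 for ICAM1, -0.16 to 0.77 for CSF3, -0.26 to 0.91 for IFI44, -0.0197 to 0.19 for ERAP2 and -0.00589 to 0.12 for TAPBP. For EZH2 between shRING1B and shBMI1 the range was -0.22 to 0.0294.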

Other observations

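Interferon-response genes differed between the arrays of the same hairpin, except with shEZH2. Averaged over 35 genes, replicate 2 lay above replicate 1 by 0.40 log2 units with shGFP, by 0.31 with shRING1B and by 0.30 with shBMI1, and by 0.01 with shEZH2. IFIT1 was at 5.87 and 7.31 on the shGFP arrays, 4.85 and 6.18 with shRING1B, 6.11 and 7.12 with shBMI1, and 4.99 and 5.26 with shEZH2. The hairpins with the difference are those whose arrays share a title prefix. This comparison was made after the values were seen and has no test, and no explanation was tested.

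Among genes that Polycomb proteins silence in many cell types, few passed over all genes. Of 27 HOX genes, HOXB9 rose with shEZH2 (log2 1.12 ± 0.09, adjusted p = 0.00489) and was at 0.59 ± 0.09 with shRING1B (adjusted p = 0.167) and 0.08 ± 0.09 with shBMI1. Of 51 developmental transcription factor genes, GATA6 rose with shEZH2 (0.81 ± 0.12, adjusted p = 0.026) and was at 0.67 ± 0.12 with shRING1B (adjusted p = 0.187) and 0.07 ± 0.12 with shBMI1. SOX2 was at 0.77 ± 0.12 with shBMI1 (adjusted p = 0.316). Neither list passed by camera in the 3 comparisons with shGFP, where the lowest adjusted p was 0.055, for developmental factors with shRING1B. The mixed form of fry, which asks whether members change in either direction and does not compare them with other genes, gave HOX genes adjusted p = 1.65e-05 with shEZH2, 0.00719 with shRING1B and 0.992 with shBMI1. For developmental factors it gave adjusted p = 0.000132, 0.00378 and 0.00498 in the same order. It called 25, 12 and 5 of 30 lists with shEZH2, shRING1B and shBMI1, so passing this test was not particular to Polycomb targets. With shEZH2 the HOX value was the lowest of the 30 lists, shared with the list of Polycomb repressive complex 1 genes. HOXB9, GATA6 and SOX2 were named after their values were seen.

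Markers of other cell types and further genes gave single increases with shEZH2, also named after their values were seen. The matrix proteoglycan DCN rose (0.93 ± 0.10, adjusted p = 0.0109), while its neighbour in the fibroblast list, LUM, was at 0.89 ± 0.23 (adjusted p = 0.12). The melanocyte antigen MLANA rose (0.64 ± 0.11, adjusted p = 0.0459). The fibroblast list had an adjusted p of 0.0935 with shEZH2, the melanocyte list 0.5 and the endothelial list 0.5. SRGN, abundant in blood cells, was at -0.82 ± 0.18 with shEZH2 (adjusted p = 0.0892) and 0.79 ± 0.18 with shRING1B (adjusted p = 0.318).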
